A study of Arabidopsis thaliana with 4 samples.

How the data were processed

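Inflorescences with unopened buds were collected from Ler and top1a-2 plants and ground, and nuclei were prepared and digested with micrococcal nuclease, per the labels' protocols. The DNA was run on an agarose gel, the band near the length of a mononucleosome was cut out, and TruSeq libraries of it were sequenced on an Illumina HiSeq2000, per the same protocols. The groups came from the series' design text and the sample titles, which give 2 replicates of each genotype. The titles number the replicates in both genotypes but name no batch, day or pool behind the numbers.

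Per the file headers, each deposited list gives for every nucleosome call its chromosome, position, fuzziness, size, confidence score and forward and reverse votes. The deposited confidence score is the caller's own value for each call, and its scaling is not given in the sources used here. The mean score was close to 1 in every library, so it carries no total depth. The aligner, the nucleosome caller, its thresholds, the genome build and whether positions count from 0 or 1 are not given in the sources used here. The calls were made separately for each library, per the 1 list deposited for each. The lists hold calls on the 5 nuclear chromosomes. The 2 columns of votes were not used. No read counts were used, so the read depth of each library is unknown, no counting interval can be given, and a difference in the number of calls between libraries can come from depth as well as from chromatin.

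The build of the lists was compared with a gene table of the assembly TAIR10.1. The last call on each chromosome lay 356 to 439 kb before the end of the last gene of the table, and 767 genes lay at least partly beyond the last calls. The lists were therefore taken to be on another build, and the table, which gives no strand, was not used for positions. For this reason the analyses planned on gene bodies, promoters, gene lists and transcription starts, and the rule for named genes, could not be run, and gene annotations of the windows are not reported here. The gene lists fixed beforehand were not tested. Coordinates are those of the deposited lists, and windows are numbered from 1.

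The measures per library were the number of calls, calls per kb, mean and median fuzziness, the share of calls with a fuzziness of up to 25 bp, the median size and score, and the distances between neighbouring calls on a chromosome. Pericentromeres were the 25 Mb within 2.5 Mb of 15, 3.6, 14, 4 and 12 Mb on chromosomes 1 to 5, and the arms were the remaining 92.2 Mb up to the last call. These positions, taken as the centromere midpoints, were fixed beforehand and were not checked against the build of the lists. Spacing was the median distance between neighbours 120 to 250 bp apart, taken over whole chromosomes because the starts of genes were not placed. Each measure was compared between the genotypes with the exact two-sided permutation test over the 6 assignments of the labels. Benjamini-Hochberg adjustment covered all 32 measures. For matched fuzziness, calls were sorted into 6 classes of distance to the nearest call, and the class means of each library were averaged with the mean class shares of the 4 libraries as weights. Position agreement was the share of calls with a call of the other library within 20 bp, averaged over both directions of a pair. The chance level was the same share with 1 library shifted by 5 kb.

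Windows of 10 kb tiled the chromosomes up to the last call, 11714 in all. The 68 windows with no call in 3 or more libraries were left out. The library means differed by up to 1.17 times, so calls per window were divided by the library mean, as fixed for means differing by more than 10 percent. Log2(level + pseudocount) was fitted with limma (version 3.58.1, variance trend, no covariate) in R 4.3.3, with a pseudocount of 0.1 of the median level, or 0.104. Fold changes are on that scale, which understates changes of sparse windows. A Benjamini-Hochberg adjusted p of 0.05 was the threshold. The sum of the scores in each window, divided by its library mean, and the mean fuzziness of windows with at least 5 calls per library were fitted in the same way and were added after the data were seen, as were the measures of fuzziness, size, score, close neighbours and gaps. The planned measures were the calls in 10 kb windows, the pericentromere to arm ratio and the spacing. Windows were to be named as the 3 with the largest change in each direction among those that passed. As none passed for calls, the 3 with the smallest p-values in each direction are named instead.

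The window test was checked on simulated data that had the call numbers and residuals of these libraries and 200 changed windows per run. For calls, 11, 17 and 0 unchanged windows were called beside the changed ones at 1.5, 2 and 1.2 times. For the summed score 94% of the windows were recovered at 1.5 times and none at 1.2 times. For mean fuzziness 71.5% were recovered at a difference of 12 bp and none at 6 bp.

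The settings fixed before the data were examined were, for the window test, quantile normalization, no division by the library mean, other pseudocounts, other filters on low levels, the replicate number as a block, no variance trend, and leaving out each library in turn. For the ratio and the spacing they were another width of the pericentromere, window medians, the mode of the smoothed distances and another range of distances. A stricter list of calls without the scores below the lower quartile was fixed for all of them. Other thresholds, window sizes and offsets, an equal number of highest-scoring calls (286541 per library), calls of 50 to 250 bp and division by the library median were added after the data were seen. The equal number was the whole list of Ler replicate 2, so that setting removed calls from the other libraries only. Values were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9.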

Results

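Nucleosome positions were mapped by micrococcal nuclease sequencing in inflorescences of Arabidopsis thaliana carrying unopened buds. Micrococcal nuclease digests the linker DNA between nucleosomes, so that the protected fragments mark where nucleosomes sit. The libraries came from the accession Landsberg erecta (Ler) and from top1a-2, a mutant of TOP1α, which is a DNA topoisomerase I and relaxes supercoils in DNA. There were 4 libraries, 2 of each genotype. The deposited data were lists of called nucleosomes, 1 list per library, each call with a position, a fuzziness (the spread of its position, in bp), a size and a confidence score. The lists held 315744 and 286541 calls in the Ler replicates 1 and 2, and 335395 and 315609 calls in the top1a-2 replicates 1 and 2. Read depth was unknown, because the lists give calls and not reads, and whether their columns of votes reflect it was not examined. The design asked how the loss of TOP1α changes nucleosome density. With 2 libraries against 2, the exact two-sided permutation test cannot go below p = 0.333, so no single value could pass a threshold of 0.05, and nothing in the labels says that the libraries came from separate pools of plants. The p-values therefore measure only the spread between these samples, which may be technical.

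On the chromosome arms, nucleosome calls lay more densely in both top1a-2 libraries than in both Ler libraries, but by a margin that was very small for the nearest pair. The arms held 2.89 ± 0.141 calls per kb (SD, n = 2) in top1a-2 and 2.64 ± 0.196 in Ler, a ratio of 1.09 (exact permutation p = 0.333). The lower top1a-2 library, at 2.789 calls per kb, stood just above the higher Ler library, at 2.783. Over the whole genome the libraries overlapped, with 325502 ± 13991 calls in top1a-2 and 301142 ± 20650 in Ler (SD, n = 2 each; exact permutation p = 0.667). The ratio was 1.08, with the lower top1a-2 library below the higher Ler library. The difference of 24360 calls was 9758 without Ler replicate 2, 38961 without Ler replicate 1 and 14467 without top1a-2 replicate 1. Single chromosomes gave no clearer separation. On chromosome 5 the lower top1a-2 library held 72027 calls and the higher Ler library 72024, and on chromosomes 3 and 4 the genotypes overlapped.

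Pericentromeres are rich in transposons and heterochromatin. Taken as the regions within 2.5 Mb of assumed centromere midpoints, they did not separate the genotypes by their density of calls. They held 2.37 ± 0.0402 calls per kb in top1a-2 and 2.30 ± 0.103 in Ler (SD, n = 2), with overlapping libraries (exact permutation p = 0.667). The pericentromeric density relative to the arms was 0.821 ± 0.0261 in top1a-2 and 0.869 ± 0.0254 in Ler, and both mutant libraries, at 0.802 and 0.839, were below both Ler libraries, at 0.851 and 0.887 (exact permutation p = 0.333). The difference in this ratio was -0.0485, larger than the SD within either genotype. It was -0.0306 without Ler replicate 2 and -0.0301 without top1a-2 replicate 1. With medians of 10 kb windows in place of means it was -0.03 and the genotypes overlapped (exact permutation p = 0.667). It shrank to -0.00975 when the calls below the lower quartile of the score were left out of each library, still without overlap (exact permutation p = 0.333). With an equal number of the highest-scoring calls in each library it was -0.0681 and the genotypes overlapped. That number is the whole list of Ler replicate 2, so this library alone was not trimmed. The library with the most calls, top1a-2 replicate 1, had the lowest ratio, and the library with the fewest, Ler replicate 2, the highest.

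Neighbouring nucleosome calls were more often close together in top1a-2. Distances under 200 bp made up 10.7% ± 1.79 of neighbouring pairs in top1a-2 and 7.59% ± 0.896 in Ler (SD, n = 2), 1.40 times as many, with all mutant values above all Ler values (exact permutation p = 0.333). The share was 11.8% and 9.01% on the arms of the mutant replicates against 7.72% and 6.32% in the Ler replicates, and 12.6% and 11.1% against 10.4% and 9.63% in the pericentromeres. The mean difference of 3.07 percentage points was 2.05, without overlap, when the calls below the lower quartile of the score were left out. It was 0.673, with overlapping genotypes, for an equal number of the highest-scoring calls, a setting that left only Ler replicate 2 untrimmed. The library with the most calls, top1a-2 replicate 1, had the largest share (11.9%), and the one with the fewest, Ler replicate 2, the smallest (6.96%). Top1a-2 replicate 2 and Ler replicate 1, with 315609 and 315744 calls, had 9.40% and 8.23%. The difference was thus not separated from the number of calls. At the other end, gaps of over 500 bp made up 9.19% and 12.7% of pairs in the top1a-2 replicates and 12% and 20.7% in the Ler replicates, so that the genotypes overlapped and the mean difference rested largely on Ler replicate 2. Without that library the difference in wide gaps was -1.06 percentage points instead of -5.39. The median distance between neighbouring calls was 314 and 335 bp in the top1a-2 replicates and 337 and 370 bp in the Ler replicates. Among neighbours 120 to 250 bp apart, a range fixed beforehand in which the distances show no maximum, so that its limits help to set the value, the median distance was 207 and 208 bp in top1a-2 and 210 and 209 bp in Ler (exact permutation p = 0.333). The difference of -2 bp was -4 bp, without overlap, when the calls below the lower quartile of the score were left out, and -2.5 bp with calls of 50 to 250 bp only. For distances of 140 to 220 bp the means were 190.5 bp in top1a-2 and 191.5 bp in Ler, and the mode of all distances was 306 against 320 bp on average, both with overlapping genotypes (exact permutation p = 0.667 each), and for an equal number of the highest-scoring calls the difference was 0.5 bp.

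**Figure D1:**
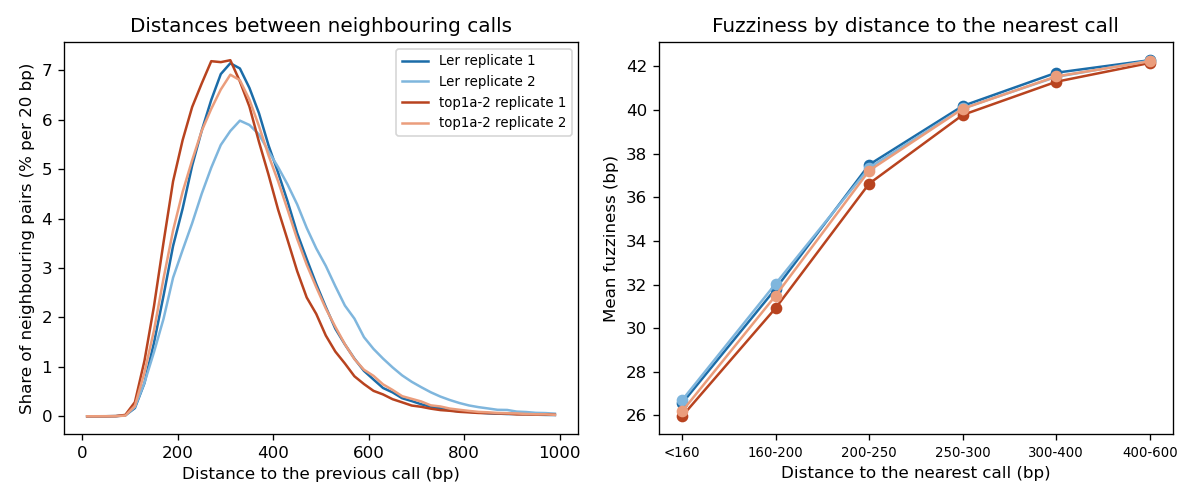
The left panel plots the distance to the previous call on the same chromosome (bp) against the share of neighbouring pairs (% per 20 bp) for each of the 4 libraries, and the right panel the mean fuzziness (bp) of calls in 6 classes of distance to the nearest call. Both top1a-2 libraries have a larger share under 200 bp (11.9% and 9.40%) than both Ler libraries (8.23% and 6.96%), and in the right panel fuzziness is lowest for calls that have a neighbour under 160 bp away.

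Nucleosome positions were called with less fuzziness in top1a-2. Mean fuzziness was 38.1 ± 0.765 bp in top1a-2 and 39.3 ± 0.289 bp in Ler (SD, n = 2), a difference of -1.20 bp that exceeded the SD within either genotype, with no overlap of the libraries (exact permutation p = 0.333). Narrow calls, with a fuzziness of up to 25 bp, made up 11.0% and 8.15% of all calls in the top1a-2 replicates and 6.74% and 5.87% in the Ler replicates, 1.52 times as many on average. On the arms the narrow share was 8.85% ± 2.20 in top1a-2 against 5.28% ± 0.727 in Ler, and in the pericentromeres 12.8% ± 1.25 against 10.6% ± 0.252. Mean fuzziness was lower in both mutant libraries than in both Ler libraries on each of the 5 chromosomes, with differences from -1.11 bp on chromosome 3 to -1.24 bp on chromosome 5. When the libraries were weighted to the same mix of distances to the nearest call, the difference in mean fuzziness was -0.310 bp, still without overlap of the genotypes (exact permutation p = 0.333). Both top1a-2 libraries were lower than both Ler libraries in each class of distance under 300 bp, though only narrowly at 250 to 300 bp. Without top1a-2 replicate 1, the library with the most calls, the differences were -0.662 bp in mean fuzziness, 1.84 percentage points in narrow calls and 1.80 percentage points in close neighbours. With an equal number of the highest-scoring calls in each library, the narrow calls and the close neighbours overlapped between the genotypes. This setting left Ler replicate 2 untrimmed, so it did not remove low-scoring calls evenly from the libraries. The median size of a call was 144.5 and 142.7 bp in the top1a-2 replicates and 144.6 and 142.4 bp in the Ler replicates, so that it followed the replicate number and not the genotype (exact permutation p = 1). In all, 32 measures per library were compared in this way, and the lowest p after Benjamini-Hochberg adjustment of the exact permutation values was 0.627.

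**Figure D2:**
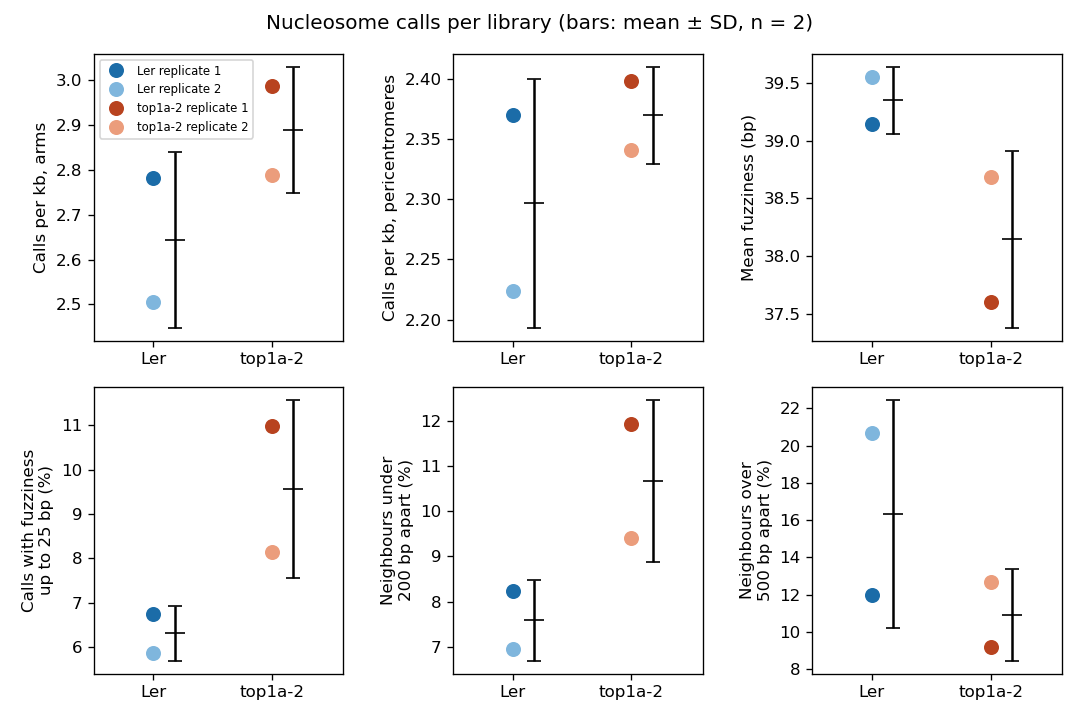
Each panel plots 1 measure of the nucleosome calls for the 4 libraries (dots, by genotype) with the mean ± SD of each genotype (n = 2) beside them, and the vertical axes do not start at 0. The genotypes do not overlap in calls per kb of the arms, in mean fuzziness (bp), in narrow calls (%) and in close neighbours (%), and overlap in calls per kb of the pericentromeres and in gaps over 500 bp (%).

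The number of calls was then compared in 11646 windows of 10 kb along the 5 chromosomes, after division by the library mean. No window passed limma's test at an adjusted p of 0.05, while 645 windows had an unadjusted p under 0.05, with 582 expected by chance. Of the 645, 333 had more calls in top1a-2 and 312 had fewer. Without the division, 8 windows passed, 4 in each direction, and 605 of the 662 at an unadjusted p under 0.05 had more calls in top1a-2. On simulated data with the spread of these libraries, the test recovered 97.5% of 200 windows with a 2 times higher call number. It recovered 53.5% at 1.5 times and none at 1.2 times, so a relative change of 1.2 times in a single window was not detectable. These rates hold for 200 windows changed at once. With fewer changed windows the adjusted threshold is stricter, and a real window with a log2 change of 1.08 did not pass (limma adjusted p = 0.112). The test therefore does not exclude changes of 2 times in a few single windows. Division by the library mean removes a difference shared by all windows, so this test could not show one between whole libraries.

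The window with the smallest p lay on chromosome 1, from 9530001 to 9540000 in the coordinates of the deposited lists. It held 26 and 30 calls in the top1a-2 replicates and 13 and 9 in the Ler replicates, a log2 change of 1.08 ± 0.21 (SE) that did not pass (limma adjusted p = 0.112). Higher call numbers in top1a-2 were followed by a window on chromosome 1 from 22280001 (34 and 32 against 18 and 17 calls) and 1 on chromosome 5 from 23640001 (35 and 36 against 27 and 13 calls), each with a limma adjusted p of 0.803. The 3 windows with lower call numbers and the smallest p-values were sparse ones. They lay on chromosome 4 from 10210001, with 1 and 2 calls in top1a-2 against 4 and 4 in Ler, and on chromosome 3 from 14020001, with 4 and 3 against 8 and 7, and from 11830001, with 3 and 7 against 11 and 9 (limma adjusted p = 0.803 in each).

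**Figure D3:**
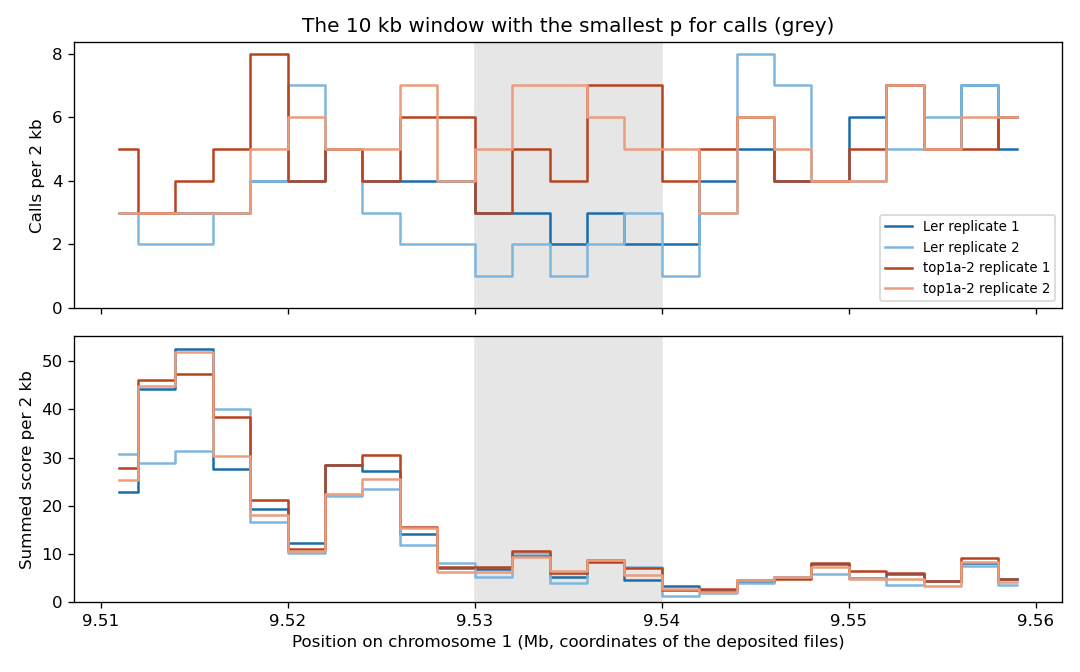
Calls per 2 kb (top) and summed confidence score per 2 kb (bottom) are plotted against the position on chromosome 1 (Mb) for the 4 libraries around the 10 kb window from 9530001 to 9540000 (grey). The window holds 26 and 30 calls in the top1a-2 libraries against 13 and 9 in the Ler libraries, while the summed score of the whole window is 39.3 and 36.3 against 34.9 and 35.3.

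Mean fuzziness was compared in the same way in 11481 windows that held at least 5 calls in each library. A single window passed limma's test, on chromosome 3 from 13790001 to 13800000, where fuzziness was 34.7 ± 4.71 bp (SE) higher in top1a-2, against the genome-wide direction (adjusted p = 0.0229). Its mean fuzziness was 64 and 50.6 bp in the top1a-2 replicates and 32.6 and 12.7 bp in the Ler replicates. The SE is limma's, which borrows from the variance of other windows, and is small beside these differences between replicates. The window held only 5 and 7 calls in the top1a-2 replicates and 5 and 6 in the Ler replicates. It did not pass without the variance trend or without the scores below the lower quartile, where the 1 window that passed was lower in top1a-2, and no window of 50 kb passed. At an unadjusted p under 0.05 stood 788 windows, of which 83 had higher fuzziness in top1a-2. The median difference over all windows was -1.24 bp, and with the libraries centred on their own mean 281 of 559 such windows had higher fuzziness in top1a-2. Without 1 library at a time, the median difference was between -1.83 bp (without top1a-2 replicate 2) and -0.694 bp (without top1a-2 replicate 1).

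Positions agreed between libraries to a similar degree within and between the genotypes. Between the Ler replicates, 21.8% of the calls had a call of the other library within 20 bp, averaged over both directions. After a shift of 5 kb the share was 10.8%, a ratio of 2.03. For the top1a-2 pair the share was 23.7% against 11.8% after the shift, a ratio of 2.01. The pairs of a Ler and a top1a-2 library gave ratios of 2.06 and 2.12 where they had the same replicate number and of 1.96 and 2.01 where they did not.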

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

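The tests of summed score and fuzziness in windows, the measures of size and score, and the settings marked as added were chosen after the data were seen. Of 119 alternatives, 90 kept the direction or, for windows, the number that passed. In 2 of them the 1 window changed in fuzziness was lower instead of higher in top1a-2. For single measures the exact permutation test used here allows no p under 0.333, so only their direction was compared. The call number, mean fuzziness, narrow calls, close neighbours, wide gaps and the pericentromere to arm ratio kept their direction under all alternatives run for them. Where the genotypes do not overlap, leaving out 1 library cannot turn the direction, so those alternatives, counted among the 90, test nothing. For the call number, whose genotypes overlap, leaving out libraries was the only alternative run. Spacing turned from -2 to 0.5 bp with an equal number of highest-scoring calls (added), and the median score from -0.0377 to 0.0128. That setting trimmed all libraries but Ler replicate 2. The median size (0.0635 bp) turned to -0.337 bp without scores below the lower quartile, to -0.006 bp with calls of 50 to 250 bp (added), and ranged from -1.03 to 1.16 bp without 1 library at a time, negative without Ler replicate 2 or top1a-2 replicate 1. Windows changed in calls numbered 8 as deposited, 9 with no filter, 1 without the variance trend and 1 without scores below the lower quartile, against 0, and 0 to 2 without 1 library (2 without top1a-2 replicate 2). Windows changed in summed score numbered 86 as deposited, 9 divided by the library median, 3 without scores below the lower quartile and 6 in windows of 5 kb, against 0, and 1 to 168 without 1 library (8 without Ler replicate 1, 1 without Ler replicate 2, 168 and 111 without top1a-2 replicates 1 and 2). Windows changed in fuzziness numbered 2 centred on the library mean, 2 with quantile normalization and 0 in windows of 50 kb, against 1, and 19 to 65 without 1 library. A lone library is then assumed to vary like the other genotype. The cause was not tested for any of these. With the replicate number as a block, 0 windows passed in calls, 718 in summed score (97 higher in top1a-2), 104 with quantile normalization too (60 higher), and 81 in fuzziness. The labels give same-numbered libraries nothing in common but the number. Their deviations still correlated across windows with r = 0.486 in summed score, against 0.080 in calls and 0.034 in fuzziness. Split by replicate number instead of genotype, 3 windows passed in calls, 0 in summed score and 3 in fuzziness. At an unadjusted p under 0.05 stood 664, 1523 and 529 windows in that split, 359, 36 and 331 in the remaining split, and 645, 914 and 788 by genotype. The alternatives planned for gene bodies, promoters, gene lists and transcription starts, and spacing downstream of starts, were not run. Unknown read depth limits all of these values.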

Other observations

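The tests in this part were chosen after the results were seen, with 3 exceptions. The calls per 10 kb window and the list of calls without scores below the lower quartile were fixed before the data were examined. The bound for single chromosomes was set before the values per chromosome were looked at, though after the difference over the whole genome was known. The confidence score is the caller's own and its scaling is not given, so comparisons of summed scores between libraries depend on how the libraries are scaled.

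A run of 27 windows on chromosome 2, from 3140001 to 3410000 (270 kb), had a high summed score in all 4 libraries and a higher one in top1a-2. It was picked as the longest stretch with a summed score, averaged over the libraries, of more than 2 times the arm median, where 1 window below that was allowed in between. Relative to the arm median, its median summed score was 7.62 and 7.01 in the Ler replicates and 14.8 and 11.2 in the top1a-2 replicates, so that top1a-2 was 1.78 times higher on average. All 27 windows were higher in top1a-2. The median score of a single call in the run was 11.6 and 12.6 times that of the arms in Ler and 25.6 and 24.1 times in top1a-2, while the calls of the run covered 65.1 and 52.7 kb in Ler and 67.7 and 51.1 kb in top1a-2. No window of the run passed the limma test of the summed score. A rise was also seen outside the run. In 73 other windows over 2 times the arm median, the median ratio to the arms was 2.73 and 2.69 in the Ler replicates and 3.35 and 4.38 in the top1a-2 replicates, a median log2 change of 0.40 with quartiles of 0.09 and 0.56. Top1a-2 replicate 2 was the highest library there, and replicate 1 in the run. A choice by the level averaged over all 4 libraries can itself favour windows that are high in top1a-2.

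A larger number of called nucleosomes in the run is argued against, since calls per window relative to the arms changed by -0.15 (log2), while the summed score changed by 0.85. A candidate explanation is DNA from an organelle whose reads were placed on the run, because the reference chromosome 2 carries a large mitochondrial insertion near its centromere. Such reads would raise all windows by the same ratio, and the SD of the log2 change over the 27 windows was 0.067. A gain of copies of the region in the mutant line would do the same, so these explanations cannot be told apart here. Under a fixed gain the mutant libraries would be level with each other. In summed score they differed by 0.43 (log2), against 0.14 for the Ler libraries. In the median score of a call relative to the arms they were nearly level, at 25.6 and 24.1 times, against 11.6 and 12.6 times in Ler. The outcome thus depends on the measure, and 2 libraries do not settle this. A change of chromatin in the mutant was not tested.

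The lower fuzziness and the larger share of narrow calls in top1a-2 were found on 5 of 5 chromosomes for mean fuzziness, which argues against a single chromosome as the source. Closer spacing of the calls may account for most of the difference, as matching on the distance to the nearest call removed 74.2% of it. Low-scoring calls stay open. The difference in fuzziness was -1.04 bp without the scores below the lower quartile (pooled SD 0.517 bp), but -0.626 bp with an equal number of highest-scoring calls. In the latter setting the difference in narrow calls was 1.11 instead of 3.26 percentage points and the genotypes overlapped in narrow calls. That setting removed no calls from Ler replicate 2, so the libraries were not trimmed evenly and it cannot decide the question. The number of calls in a library stays open too, since top1a-2 replicate 2 and Ler replicate 1, which differed by 135 calls, differed by -0.457 bp, less than the pooled SD of 0.578 bp. Whether depth, digestion or the genotype set the number of calls was not tested, as the lists hold no reads.

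In the 333 windows with more calls in top1a-2 at an unadjusted p under 0.05, the median log2 change in calls was 0.41, and the median change of their summed score was -0.04, against -0.05 for all windows, a difference of 0.0079. As the 645 windows at that p were close to the 582 expected by chance, this does not decide whether more DNA came from these windows, and no biological explanation was tested.

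In windows of 10 kb the summed score passed limma's test in none of 11646, with 914 at an unadjusted p under 0.05, of which 88 were higher in top1a-2. With the libraries divided by their median instead of their mean, 267 of 464 were higher and 9 passed, so the direction depends on the scaling. Without 1 library at a time, the median log2 change over all windows was between -0.0821 (without top1a-2 replicate 1) and -0.0168 (without top1a-2 replicate 2), against -0.0480 with all libraries. The windows passing in such fits cannot be set against the count of 0, since a lone library is assumed to vary like the other genotype. The strongest call, on chromosome 3 at 13408783 in the first Ler library, had a score of 1493 and 1839 in the Ler replicates and 1624 and 3292 in the top1a-2 replicates.

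Calls of different libraries lay apart by preferred distances in every pair of libraries. Densities were taken relative to the density of distances between 1000 and 1200 bp in the same pair, and not to random placement. On that scale the density was between 1.94 and 2.10 below 20 bp and fell to a minimum of 0.747 to 0.783. It was 0.803 to 0.825 between 160 and 200 bp and had a further maximum of 1.08 to 1.10 between 320 and 360 bp.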
